A study of Arabidopsis thaliana with 6 samples.

How the data were processed

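RNA of the vegetative part of Arabidopsis thaliana Col-0 seedlings was measured on ATH1 oligonucleotide arrays, which carry short probes for most of the protein-coding genes known when they were designed. The series holds 6 arrays, 3 from wild-type plants and 3 from plants that overexpress GRF5 from the strong 35S promoter (35S::GRF5). The labels call the 3 samples of each group biological repeats. Per the labels, plants of growth stage 1.03 were raised in vitro on MS medium with 16 h of light and 8 h of dark at 22 °C, and RNA was isolated on silica columns.

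The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which state no version. RMA corrects background, equalises the distributions of probe values between arrays and summarises the probes of each transcript. The table has 1 row for each of 20777 Arabidopsis locus codes and not the array's own probe set names. The map from probes to loci is not given in the sources used here, nor is the set of arrays normalised together. Scanner files and detection calls were not used here, so a low value cannot be separated from background. No batch, plate or scan date was used, since the labels give none. The values had no missing entries and no 2 identical rows. A gene reference table of the TAIR10.1 assembly was used for names only: 20508 locus codes were found in it and 269 were not, and the latter keep their locus code. Each array contributes 1 value per gene with no count behind it, so the number of arrays limits the precision: the median 95% interval of a difference reached 0.23 log2 units to either side, a factor of 1.17.

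Groups were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust estimation, two-sided), with Benjamini-Hochberg adjustment over all 20777 loci and a threshold of 0.05. Every difference is 35S::GRF5 minus wild type, and a fold is 2 to the power of that difference. No filter on low values was applied. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and limma's rotation test fry beside it. The lists held 499 entries, of which 9 were left out because the locus did not carry the listed name, 48 were not in the table and 442 were measured. The interval given for a list is the 95% interval of the difference between group means of the per-array list mean. The planned test of gene families taken from gene descriptions was not run, because the reference table used here pairs loci with names and no descriptions. The planned design assumed probe sets; as each row is a locus, the steps that choose between probe sets were not needed.

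The grouping, the tests, the 29 lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took GRF5 in every array, the other GRF and GIF genes, the 10 largest increases and the 10 largest decreases among called genes with non-overlapping groups, and up to 4 members with the smallest p from each list that passed its test or held a called gene. Alternatives were the replicate number as a block, filters on low mean values at the 25th percentile and at the median, centring of each array on its median, quantile normalization, eBayes with trend and robust estimation, array weights, a 2-fold minimum, each gene's own variance, the other list tests, and leaving out each array in turn. Leaving the GRF5 gene out of every list was added after the data were seen.

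The scripts were tested on simulated data in 10 runs over 20777 genes. The spread of each gene was that of the real arrays after limma's moderation, which draws extreme spreads towards a common value. Each run held 200 changed genes, and lists of 13 genes shifted by 0.3 came in addition to these. The fit called 62.5% of simulated changes of 0.5 log2 units, 99.9% of those of 1 and 100% of those of 2, and 0.0763% of unchanged genes. Camera called 200 of 200 simulated lists shifted by 0.3 and 2 of 200 lists with no shift. These simulated genes were drawn independently, so the list rates do not cover correlated genes. The rates for single genes hold for the simulated values and may differ in the real data, where noisy genes keep their full spread. Array weights estimated from the real values ran from 0.469 in 35S::GRF5 replicate 1 to 2.04 in wild type replicate 1. How such unequal arrays change the rates was not tested.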

Results

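Transcript levels were measured in seedlings of wild-type Arabidopsis and of a line overexpressing GRF5, a transcription factor of the growth-regulating factor family that promotes cell proliferation in leaves. The series title places the line among several that form larger leaves, and the comparison asks which transcripts differ from wild type in the vegetative part of the seedling. Each group had 3 arrays. Array medians on the log2 scale separated by group, at 6.38 to 6.39 in wild type and 6.41 to 6.43 in 35S::GRF5. Correlations across loci ranged from 0.993 to 0.997 within groups and from 0.990 to 0.995 between groups. The first principal component held 39.1% of the variance and placed the wild-type arrays at -18.7 to -10.5 and the 35S::GRF5 arrays at 8.73 to 20.9.

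GRF5 (AT3G13960) read 4.73, 4.75 and 4.26 in wild-type replicates 1 to 3 and 11.3, 11.4 and 12.1 in 35S::GRF5 replicates 1 to 3. The difference was 7.03 log2 units (95% interval 6.58 to 7.47, n = 3 per group), a factor of 131, with an adjusted p of 2.98e-07. The wild-type mean was low, with 28.5% of all loci below it, so the factor depends on a value near the bottom of the array's range. Among the other 10 measured members of the list of GRF genes and of GIF genes, their transcriptional coactivators, 0 passed limma over all genes and 1 was lower adjusted over the list alone, beside GRF5 as the 1 that was higher; 3 of the 11, GRF5 included, had an unadjusted p under 0.05. The lower gene was GRF3, with a difference of -0.65 (-0.92 to -0.37) and an adjusted p of 0.0502 over all genes. GRF3 passed with trend and robust estimation (adjusted p = 0.0381), over loci above the 25th percentile (0.0457), with array weights (0.037) and without 35S::GRF5 replicate 3 (0.035); without any other single array its adjusted p was 0.087 to 0.204. GIF2 differed by 0.28 (adjusted p = 0.22) and AN3, also called GIF1, by 0.14 (adjusted p = 0.709). GRF1, GRF2 and GRF4 differed by 0.17, 0.15 and 0.15, GRF6, GRF7 and GRF8 by -0.04, -0.14 and -0.16, and GIF3 by -0.21; without 35S::GRF5 replicate 2, GRF1 differed by 0.03, GRF4 by 0.0042 and AN3 by -0.03, and without wild type replicate 3 GRF2 differed by 0.07 and GRF8 by -0.07. Without 35S::GRF5 replicate 1, GRF7 differed by -0.02, GIF3 by -0.13 and GRF6 by 0.05, so the size of none of these 8 held over the arrays. As a group the list did not pass camera (adjusted p = 0.582).

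Of 20777 loci, 160 (0.77%) passed the threshold, 59 higher and 101 lower in 35S::GRF5. Of these, 7 genes were at least 2-fold higher and 21 at least 2-fold lower. The median called difference was 0.65 among higher genes and -0.76 among lower ones. The 35S::GRF5 arrays had the higher medians, and the median difference of all loci was 0.024. With each array centred on its median, that difference was -0.014 and the calls split into 45 higher and 126 lower. Counts by direction therefore depend in part on this offset. At an unadjusted p under 0.05 there were 3212 loci, 1972 higher and 1240 lower, where chance alone gives about 1039. Counts at this p within a list are to be read against that share of all loci. Counts adjusted over a list alone correct neither for this excess nor for the number of lists. The groups did not overlap for any of the 160 called genes, and for 21.7% of all loci, where chance gives 10%. The count varied with the array left out. It was 17 without wild type replicate 1, 96 without wild type replicate 2, 50 without wild type replicate 3, 63 without 35S::GRF5 replicate 2 and 69 without 35S::GRF5 replicate 3, and without 35S::GRF5 replicate 1 it was 186, of which 99 were higher. Such a fit has fewer values, so a lost call can reflect lower precision and not a smaller difference. Wild type replicate 1 lay closest to its group mean (root mean square deviation 0.101) and 35S::GRF5 replicate 1 farthest (0.162). Without wild type replicate 1, the 28 called genes of the naming rule all kept their direction, and 12 stayed past the threshold.

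**Figure D1:**
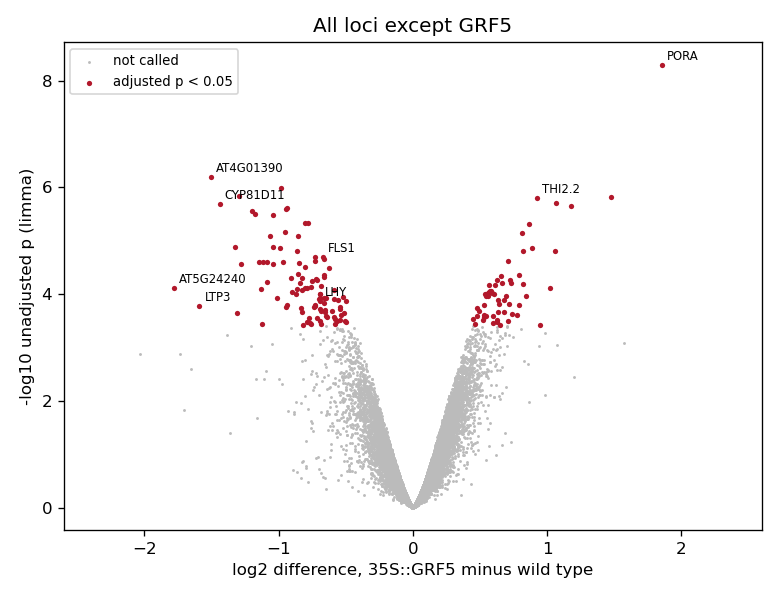
Unadjusted p of limma (as -log10, vertical axis) against the log2 difference between 35S::GRF5 and wild type (horizontal axis) for every locus except GRF5, which lies outside the range at 7.03. Red points are called genes. PORA stands apart at 1.86.

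The largest increase after GRF5 was that of PORA, a protochlorophyllide oxidoreductase of chlorophyll synthesis, which rose 3.63-fold from 7.05 ± 0.15 to 8.90 ± 0.01 (log2 mean ± SD, n = 3; adjusted p = 5.22e-05). AT4G30450 rose 2.78-fold, AT1G12080 2.27-fold, and AT1G62290, which encodes an aspartyl protease, 2.09-fold. AT2G16660 also rose 2.09-fold, and AT5G44400, of the berberine bridge enzyme-like family, 2.03-fold. The calcium-dependent protein kinase gene CDPK2 (AT1G35670) rose 1.93-fold, the thionin gene THI2.2 1.90-fold and the methylesterase gene MES17 1.85-fold. PORA, AT4G30450, AT1G12080, AT1G62290 and THI2.2 stayed past the threshold whichever array was left out. Without wild type replicate 1, AT2G16660 had an adjusted p of 0.0783, MES17 of 0.0698, and AT5G44400 and CDPK2 of 0.12 each. AT5G44400 was past the threshold only without 35S::GRF5 replicate 1, and CDPK2 only without wild type replicate 2, among the fits that leave out an array.

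The largest decrease was that of AT5G24240, 3.43-fold, from 6.81 ± 0.69 to 5.03 ± 0.11 (adjusted p = 0.0236). The lipid transfer protein gene LTP3 fell 3.01-fold, AT4G01390 2.83-fold and the cytochrome P450 gene CYP81D11, which is induced by foreign chemicals, 2.71-fold. AT5G03545, the phosphate starvation transcript At4, fell 2.50-fold, and AT5G20790 2.48-fold. LEA3 (AT1G02820), of the late embryogenesis abundant proteins, fell 2.45-fold, AT1G19960 2.42-fold, the cation exchanger gene CAX7 2.29-fold and AT1G64360 2.26-fold. AT4G01390, CYP81D11, LEA3, CAX7 and AT1G64360 stayed past the threshold whichever array was left out. LTP3 missed it in each such fit (adjusted p 0.0536 to 0.081), AT5G20790 in all but the fit without wild type replicate 2 (0.0644 to 0.168), and AT5G24240 without wild type replicate 3 (0.0749) or 35S::GRF5 replicates 2 (0.0708) or 3 (0.0818). Without wild type replicate 1, AT5G03545 had an adjusted p of 0.0503 and AT1G19960 of 0.0783; AT1G19960 also missed without wild type replicate 3 (0.0507) or 35S::GRF5 replicate 2 (0.0557). With trend and robust estimation AT5G24240 (0.0516), LTP3 (0.069) and AT5G20790 (0.0524) missed it too.

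**Figure D2:**
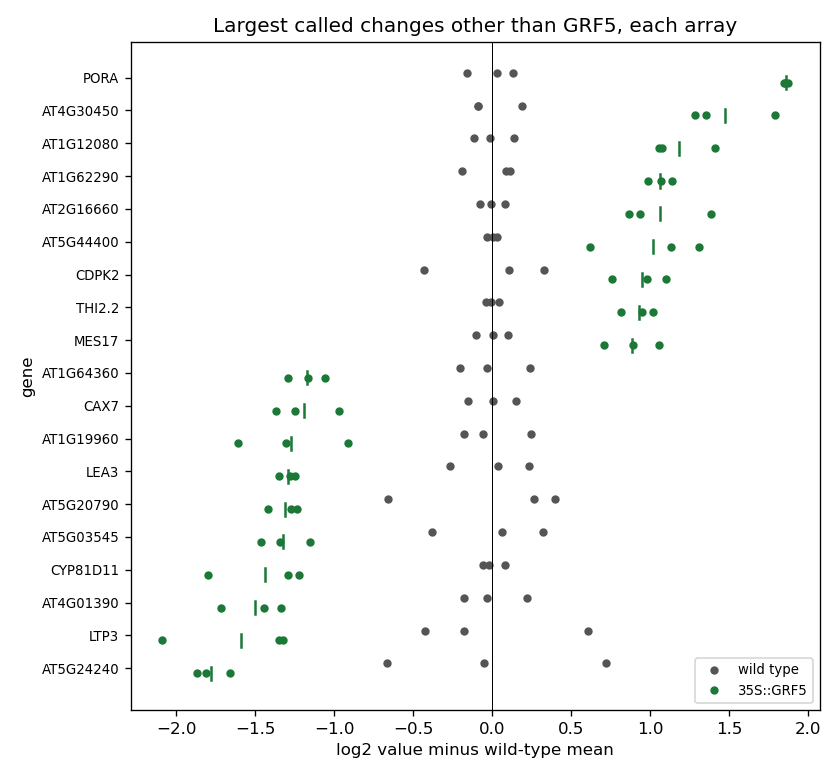
Log2 value of each array minus the wild-type mean of the gene (horizontal axis) for the called genes with the largest increases and decreases other than GRF5 (vertical axis). Each point is an array, grey for wild type and green for 35S::GRF5, and the green bar is the 35S::GRF5 mean. The 35S::GRF5 arrays of PORA lie close together (SD 0.014).

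Genes of flavonoid and anthocyanin synthesis passed camera towards lower values at the preset correlation (adjusted p = 3.94e-05), but had an adjusted p of 0.594 with an estimated correlation and an adjusted p of 0.131 in fry. At the preset correlation, camera called 3 to 8 lists in each of the other 9 splits of the arrays into 3 and 3, against 2 in the real one. Of 12 measured members, 11 had a negative difference, 2 fell over all genes and 6 were lower adjusted over the list alone; the median difference was -0.45. The called members were FLS1, flavonol synthase, with a difference of -0.67 (-0.87 to -0.48, adjusted p = 0.0137), and F3H, flavanone 3-hydroxylase, with -0.66 (-0.85 to -0.46, adjusted p = 0.0138). DFR, dihydroflavonol reductase of the anthocyanin branch, differed by -1.17 (adjusted p = 0.124), and TT5, chalcone isomerase, by -0.36 (adjusted p = 0.212). The list mean was lowest in 35S::GRF5 replicate 1, at 5.87 against 6.26 and 6.22 in the other replicates of the line, and without that array DFR differed by -0.74 and TT5 by -0.24. FLS1 missed the threshold without wild type replicate 1 (adjusted p = 0.0698) or 3 (0.0519), and F3H without wild type replicate 1 (0.0899) or 3 (0.056) or 35S::GRF5 replicate 3 (0.0503).

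The list of touch and rapid stress response genes, which are induced within minutes of mechanical disturbance, also passed camera towards lower values (adjusted p = 0.0127), with an adjusted p of 0.762 with an estimated correlation and of 0.691 in fry. Of 15 measured members 0 were called by limma, over all genes or adjusted over the list alone, and the median difference was -0.31. ERF4 differed by -0.47 (unadjusted p = 0.00593), RHL41 by -0.19 (unadjusted p = 0.0487), the calmodulin-like gene TCH3 by -0.79 and the jasmonate repressor gene JAZ1 by -0.31. Wild type replicate 3 stood apart: the list mean was 7.19 in that array and 5.40 to 5.83 in the other 5, and all 15 members had their highest value there. Without it TCH3 differed by -0.10 and JAZ1 by -0.04, the direction of the list turned and the adjusted p was 0.255; it was also above the threshold without 35S::GRF5 replicate 2 (0.0743) or 3 (0.0523) and with arrays centred on their medians (0.0607). No difference between the groups in these genes can be read from the list's call.

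**Figure D3:**
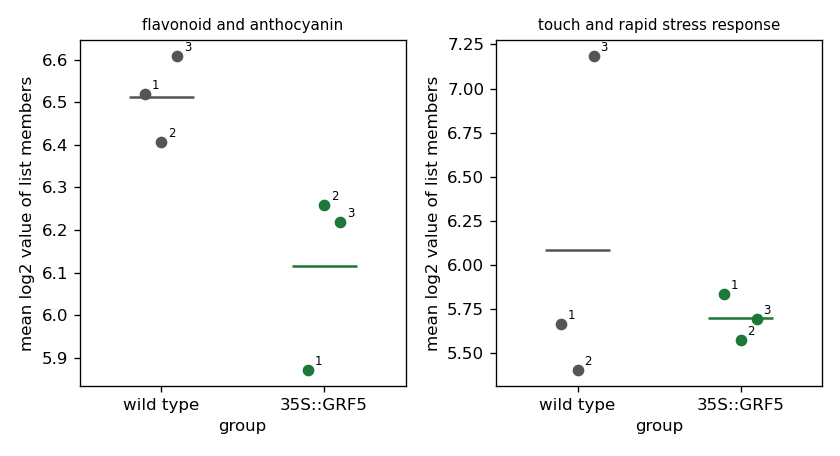
Mean log2 value of the members of the flavonoid and anthocyanin list (left) and of the touch and rapid stress response list (right) in each array (vertical axis) by group (horizontal axis), with replicate numbers; bars are group means, and the vertical axes differ and do not start at 0. In the touch list wild type replicate 3 lies at 7.19 and the other arrays at 5.40 to 5.83.

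Other lists held a called gene without passing camera. Among 22 photosynthesis and chlorophyll genes, PORA alone rose, over all genes and adjusted over the list alone. GNC, CHLD (named ALB1 in the reference table) and GLK2 differed by 0.49, 0.29 and 0.20 (adjusted p = 0.141, 0.186 and 0.318). The median difference of the list was 0.09, and its adjusted p was 0.111. Among 14 trichome and stomata markers, TMM, a receptor-like protein of the stomatal lineage, rose 1.56-fold (adjusted p = 0.031). Adjusted over the list alone 3 were higher, TMM, ER (difference 0.44) and SPCH (0.40), and the trichome regulator gene GL2 was lower (-0.41); the list's adjusted p was 0.134. Over all genes ER passed with array weights (adjusted p = 0.0408) and without 35S::GRF5 replicate 1 (0.0421), and GL2 with array weights (0.037). TMM missed the threshold without wild type replicate 1 (adjusted p = 0.145) or 3 (0.0961) or 35S::GRF5 replicate 2 (0.0992) or 3 (0.0891).

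Of 12 circadian clock genes, LHY, a morning transcription factor, fell 1.61-fold (adjusted p = 0.0286) and was the 1 lower adjusted over the list alone. CCA1 and RVE1, also morning genes, differed by -0.32 (adjusted p = 0.297) and -0.31 (0.204), and the evening gene GI by 0.16 (0.462), or by 0.10 without 35S::GRF5 replicate 2. The list's adjusted p was 0.238. Without wild type replicate 1, CCA1 differed by -0.16. LHY missed the threshold without wild type replicate 1 (adjusted p = 0.134) or 3 (0.0961) or 35S::GRF5 replicate 2 (0.0983) or 3 (0.0814).

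Of 15 salicylic acid and defence genes, PR5, a pathogenesis-related protein gene, fell 1.63-fold (adjusted p = 0.0271), the 1 lower adjusted over the list alone; WRKY70 differed by -1.16 (adjusted p = 0.224), with a wild-type SD of 1.05, and by -0.56 without wild type replicate 3. PAD3 differed by -0.18, or by -0.11 without that array, and ALD1 by -0.15, or by -0.07 without wild type replicate 1. Of 21 cell wall expansion genes, EXPB1, a beta-expansin gene, fell 1.41-fold (adjusted p = 0.0467), again the 1 lower adjusted over the list alone, while XTH24, EXLA1 and EXPA10 differed by -0.50, -0.69 and -0.39 (adjusted p = 0.2, 0.206 and 0.218); without wild type replicate 3, XTH24 differed by -0.31 and EXLA1 by -0.38. Of 12 glucosinolate synthesis genes, MYB29, a regulator of aliphatic glucosinolates, rose 1.71-fold (adjusted p = 0.0398). CYP83B1 (-0.36) was lower adjusted over the list alone, where MYB29 was the 1 higher; MYB34 differed by 0.32 and CYP79B2 by -0.56, or by -0.25 without 35S::GRF5 replicate 1. Of 9 heat shock genes, HSP18.2 rose 1.36-fold (adjusted p = 0.044), the 1 higher adjusted over the list alone; AT5G48570, HSP70 (AT3G12580) and HSFA2 differed by 0.33, -0.47 and 0.20, and without wild type replicate 3 HSP70 differed by -0.28, and without 35S::GRF5 replicate 3 AT5G48570 by 0.22. The adjusted p of these 4 lists in camera were 0.0758, 0.109, 0.961 and 0.134. Without wild type replicate 2 the first 2 passed, at 0.0107 each, but over all arrays their adjusted p with an estimated correlation were 0.594 and 0.598. With the replicate number as a block the salicylic acid and defence list had a camera adjusted p of 0.0459. Leaving out single arrays ended the call of HSP18.2 in all 6 fits (adjusted p 0.0614 to 0.208), of PR5 in all but that without 35S::GRF5 replicate 3 (0.0519 to 0.147), and of EXPB1 (0.1 to 0.213) and MYB29 (0.106 to 0.124) in all but that without 35S::GRF5 replicate 1.

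Cell division genes, of interest for a factor that acts on proliferation, did not shift as a group beyond the threshold. RNA of the vegetative part mixes all its cells, so a change limited to dividing cells could go unseen. Of 32 S-phase genes and 26 mitotic genes, 0 passed limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 6 and 3, beside 3212 of all 20777 loci. Their median differences were 0.06 and 0.05 and their adjusted p in camera 0.111 and 0.591. The S-phase list passed without wild type replicate 2 (adjusted p = 0.0107) or without 35S::GRF5 replicate 1 (0.00313), and over all arrays had an adjusted p of 0.762 with an estimated correlation and of 0.493 in fry. Of 12 cell cycle inhibitor and endocycle genes, 0 passed over all genes, 2 had an unadjusted p under 0.05, and SIM (-0.50) was lower adjusted over the list alone (camera adjusted p = 0.134). Of 24 leaf size regulators 0 passed by either count and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.582). Of 12 leaf polarity genes, 11 of them with positive differences, 0 passed by either count and 2 had an unadjusted p under 0.05 (0.133). SIM, like the genes named in the next 2 paragraphs, was named after its values were seen.

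Of the 24 cytokinin response genes, 15 with positive and 9 with negative differences, 0 passed limma over all genes. There were 8 at an unadjusted p under 0.05, beside 3212 of all 20777 loci, and 7 were higher adjusted over the list alone. The median difference was 0.16 and the camera adjusted p 0.0758, which became 0.0299 without wild type replicate 2, 0.0235 without 35S::GRF5 replicate 1 and 0.0153 over loci above the 25th percentile of mean level, but 0.243 without 35S::GRF5 replicate 3. Over all arrays that list had an adjusted p of 0.594 with an estimated correlation and of 0.0813 in fry. Of 11 jasmonate response genes 0 passed over all genes, and the 3 with an unadjusted p under 0.05 were lower adjusted over the list alone: PDF1.2 (-0.57), JAZ9 (-0.53) and LOX2 (-0.43, or -0.29 without 35S::GRF5 replicate 1). That list had a camera adjusted p of 0.0758, and of 0.0404 without wild type replicate 1, 0.0132 without wild type replicate 2 and 0.0177 over loci above the 25th percentile, but of 0.218 without wild type replicate 3. With the replicate number as a block the list's camera adjusted p was 0.0459. With an estimated correlation its adjusted p was 0.594 and in fry 0.261. Of 19 gibberellin genes 0 passed over all genes, 5 had an unadjusted p under 0.05, and GASA4 (0.43) and GA3OX1 (0.41) were higher adjusted over the list alone (camera adjusted p = 0.386); GASA4 passed over all genes without 35S::GRF5 replicate 1 (0.0407). Of 20 auxin response genes and 12 brassinosteroid genes 0 passed by either count, with 2 in each at an unadjusted p under 0.05 (0.539 and 0.599).

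The remaining lists held 0 genes called by limma over all genes. Adjusted over the list alone, 2 of 15 senescence genes were lower, SAG29 (-0.998) and SAG14 (-0.62), with a camera adjusted p of 0.582; SAG29 passed over all genes without 35S::GRF5 replicate 2 (adjusted p = 0.0443). The ferritin gene FER1 (0.83) was the 1 of 10 iron homeostasis genes that was higher (0.582). At an unadjusted p under 0.05 these lists held 5 and 4. The counts were 0 for 13 cold and drought genes (0.128), 13 ribosome biogenesis genes (0.134) and 10 plastid division genes (0.95), with 2, 2 and 1 at an unadjusted p under 0.05. The cold and drought list passed camera without wild type replicate 1 (adjusted p = 0.00153), towards lower values, but its direction turned without wild type replicate 2 (0.779); the list mean in that array was 8.54 against 7.87 to 8.17 in the other 5 arrays. The ribosome biogenesis list passed without wild type replicate 2 (0.0275), towards higher values. Both had an adjusted p of 0.762 over all arrays with an estimated correlation. Markers of other tissues gave 0 by either count: 13 root markers had a mean difference of -0.01 (-0.15 to 0.14), 11 seed storage markers of -0.01 (-0.14 to 0.12), 10 shoot apical meristem markers of -0.05 (-0.20 to 0.09), and 12 flowering and floral organ markers of 0.03 (-0.10 to 0.15). Their adjusted p were 0.591, 0.582, 0.238 and 0.852, and at an unadjusted p under 0.05 they held 2, 0, 3 and 2 genes. The seed storage and flowering lists had mean levels of 3.88 and 4.35, below the 25th percentile of all loci (4.38). In single arrays these list means were 3.78 to 3.94 and 4.26 to 4.40, with no sign of much seed or floral tissue in either group. As low values cannot be separated from background here, a small share in 1 group could go unseen.

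**Figure D4:**
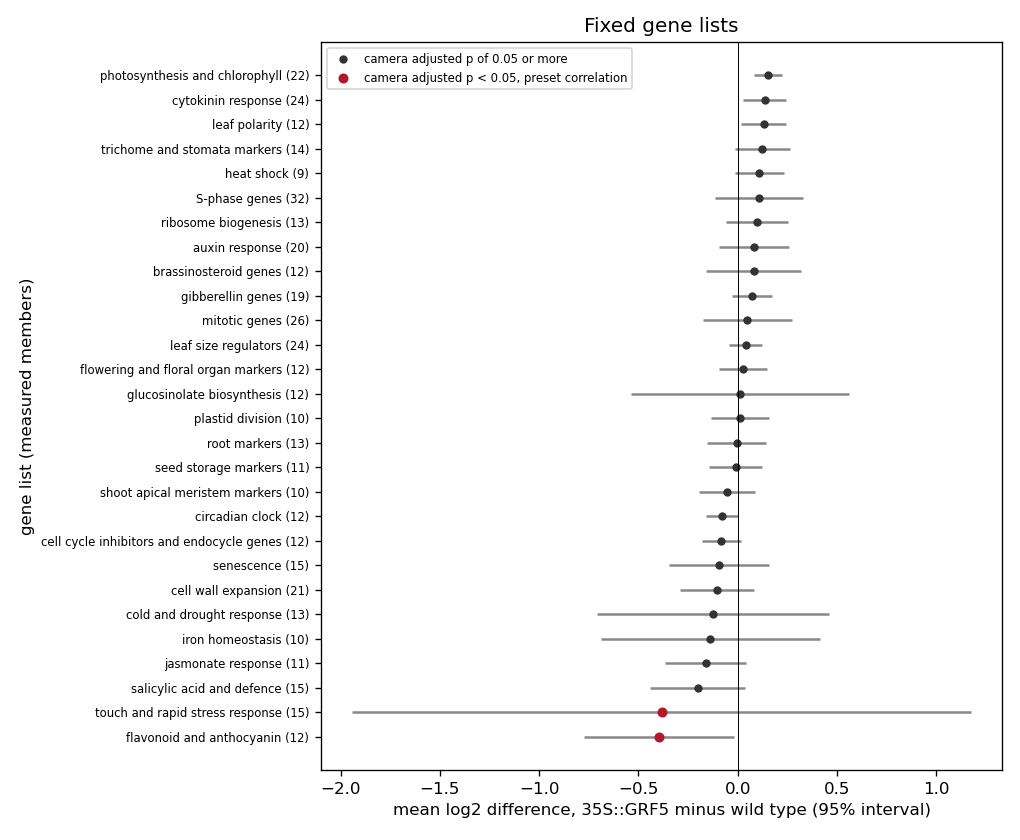
Mean log2 difference between 35S::GRF5 and wild type (horizontal axis) for the fixed lists other than the GRF list (vertical axis, with measured members). Points are means, lines 95% intervals over the arrays, and red marks lists past camera's threshold at the preset correlation. The interval of the touch list runs from -1.94 to 1.18.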

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

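Leaving the GRF5 gene out of every list was chosen after the data were seen. Both list calls stayed, which is no test of them, since GRF5 belongs to neither list. The GRF list turned from higher to lower, with a camera adjusted p of 0.599. Of the alternatives to the 160 calls (59 higher, 101 lower), both filters, centring and quantile normalization gave 165 to 171 calls. Trend and robust estimation gave 252 (116 higher) and array weights 294 (134 higher, 160 lower). A 2-fold minimum left 28 (7 higher, 21 lower), fewer by construction. With each gene's own variance in place of limma's moderated one, 0 genes passed in total, 0 higher and 0 lower, with 2656 at an unadjusted p under 0.05; this test has only the spread of its own 6 values. Leaving out single arrays gave 17 to 186 calls, 6 to 99 higher and 11 to 87 lower; the lowest was without wild type replicate 1. Of the 28 named called genes, all kept their direction in each of 10 alternatives and 11 stayed past the threshold in all 10. Trend and robust estimation ended the calls of AT5G24240 (adjusted p = 0.0516), LTP3 (0.069), AT5G20790 (0.0524) and HSP18.2 (0.0773).

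Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.053, 0.058 and -0.106, and 1 wild-type and 1 35S::GRF5 array correlated best with its own number. With the replicate number as a block, 114 genes passed, 36 of them higher, and CDPK2 (adjusted p = 0.0854), PR5 (0.0715), EXPB1 (0.0805), MYB29 (0.0806) and HSP18.2 (0.102) were not among them.

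Of the 29 lists, 2 passed at the preset correlation and 0 with an estimated correlation or in fry for a shift in 1 direction. In fry for change in either direction 14 passed. Neither form of fry compares a list with other genes, as camera does. With the block or the filter at the 25th percentile 4 passed, with centred arrays 1, and without single arrays 1 to 8. The flavonoid list had an adjusted p of 0.594 with an estimated correlation and 0.131 in fry, and stayed past the threshold without any array (5.4e-06 to 0.00331). The touch list had 0.762, 0.691 and, with centred arrays, 0.0607; without single arrays it ran from 2.43e-06 to 0.255, the last without wild type replicate 3, where its direction turned. The cause of the other changes was not tested. The 2 alternatives on probe sets and those on description families were not run. Without detection calls, what low signal limits is unknown.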

Other observations

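Chosen after the results were seen were the genes named in the next 2 paragraphs, the phosphate and sulfur tests, the test for a mislabelled array and the second list of touch genes, which was written before its own values were looked at. The tests on harvest time and on LHW targets also start from changes seen in the results. For 3 tests, those on sulfur genes, root markers and LHW targets, the reading was also made stricter after the values were seen, and the reading first written is given beside each.

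Called genes outside the naming rule were picked by eye, and no theme among them was tested for enrichment. Those that rose included the bHLH genes HEC1 (1.64-fold), LHW (1.47-fold) and AT1G68810, also called T5L1 (1.53-fold), the root and bundle sheath regulator gene SHR (1.45-fold), the zinc finger homeodomain genes HB31 and HB33 (1.55-fold and 1.60-fold), the D-type cyclin gene CYCD1;1 (1.49-fold) and AMP1 (1.58-fold), whose loss alters leaf initiation. Among cytokinin genes, the 7 that were higher adjusted over the list alone were the response regulators ARR8, ARR16 and ARR4 (differences 0.68, 0.47 and 0.44), the receptors WOL and HK2 (0.49 and 0.29), CRF5 (0.53) and the cytokinin oxidase CKX5 (0.28). These 7 were named for being higher, and 9 of the 24 genes of that list had negative differences. Without 35S::GRF5 replicate 1, ARR16 and WOL passed over all genes (adjusted p = 0.0355 and 0.0413).

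Those that fell included the homeodomain gene BLH1 (2.06-fold), the DOF factor gene OBP4 (1.61-fold), the cytochrome P450 gene CYP78A9 (1.59-fold), the NAC factors NAC102 (1.93-fold) and ATAF1 (1.58-fold), the glutathione transferase GSTU1 (2.09-fold), the aldo-keto reductases ChlAKR (1.98-fold) and AKR4C8 (1.66-fold), sucrose synthase SUS1 (1.72-fold), DMR6 (2.18-fold), ICS2 (1.87-fold) and QQS (2.18-fold). Of the 20 called genes in these 2 paragraphs, 0 kept the call in every fit that leaves out an array: 0, 11 and 7 kept it without wild type replicates 1, 2 and 3, and 17, 7 and 7 without 35S::GRF5 replicates 1, 2 and 3.

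Of 17 phosphate starvation genes 4 fell (At4, PAP17, G3Pp1 and SRG3, where 0.0826 are expected; two-sided Fisher's exact p = 1.19e-06, on genes noticed first), and among the 13 not called the median difference was -0.11, 12 of them negative, with a mean of -0.18 (-0.27 to -0.09), a camera p of 7.91e-05 and of 0.0199 with an estimated correlation. Leaving out any array kept the mean between -0.20 and -0.16. Of the 4 calls, 0 held without wild type replicate 1 and 3 without wild type replicate 2. In each of the fits without wild type replicate 3 or 35S::GRF5 replicates 2 or 3, 1 held. The list was written after its called genes were seen, so the Fisher p gives no support. Neither camera p is adjusted. At the preset correlation, camera called 3 to 8 of the fixed lists in every split of the arrays other than the real one. The values meet the criterion set for a weaker phosphate starvation response in 35S::GRF5, which stays a hypothesis. Part of the shift rests on low values. Among the members not called, SPX3, PHT1;4, RNS1, PS2 and PEPC1 lay below the 25th percentile of all loci (4.38) in both groups, and PLDP2 in 35S::GRF5. Of 13 sulfur deficiency genes 3 fell (LSU2, SDI1 and BGLU28; 0 without wild type replicate 1, 2 without wild type replicate 3 or 35S::GRF5 replicate 2), and the 10 not called had a median of -0.28 and a camera p of 5.92e-06, which meets the criterion first written; as the interval of their mean runs from -0.80 to 0.13 and the p with an estimated correlation is 0.0825, this part is left open. Without 35S::GRF5 replicate 1 that mean moves from -0.33 to -0.18 and its camera p to 0.00581; without the other arrays the mean runs from -0.45 to -0.30. A difference in medium between plates may also account for both, and was not tested because the labels name no plates.

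LHY was lower and PORA higher in 35S::GRF5, and harvest at another time of day may account for such a pair. The mean of the dawn genes CCA1, RVE1 and RVE8 minus that of the evening genes TOC1, GI, ELF4 and PRR5 differed by -0.339 (-0.825 to 0.148), so the interval holds both 0 and -0.345, the bound of 0.5 times the LHY change. The dawn genes alone differed by -0.25 (-0.48 to -0.02) and the evening genes by 0.09. Time of harvest and genotype therefore cannot be told apart for LHY and PORA, and an effect of GRF5 on the clock was not tested.

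In wild type replicate 3 the touch genes were high: ERF104 read 9.30 there against 6.70 at most elsewhere, and STZ 7.65 against 4.95. A swap with a 35S::GRF5 array is argued against by GRF5, which lay 7.07 log2 units below the lowest such array (difference -7.07). Handling shortly before harvest may be the source. The second list of 15 touch and wound genes had a mean of 5.33 in that array, 0.49 above the highest of the others, which falls just short of the 0.5 set beforehand, and 8 of its 15 members were highest there; this stays open.

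Root tissue left in 1 group would move root markers, whose mean differed by -0.0053. That interval, -0.15 to 0.14, lies within the bound of 0.3 first written as excluding it. The list thus shows no common shift. Only 1 of the 13 markers lay above the median of all loci, and the highest mean among the others was 5.03. As a low value cannot be separated from background here, a small share of root could go unseen. The marker above the median, PYK10, was higher in 35S::GRF5 by 0.35 (0.08 to 0.62, adjusted p = 0.209), and by 0.22 without 35S::GRF5 replicate 3. Its groups did not overlap, as for 21.7% of all loci, so this 1 gene decides nothing. The matter is read as open. Higher LHW and T5L1 would be followed by higher LOG3, LOG4, AHP6 and ACL5 if the output of that pair rose. Their mean differed by 0.026 (-0.11 to 0.16) with 2 of 4 positive, which meets the bound of 0.2 first written as excluding it; as 2 of the 4 lay below the 25th percentile of all loci, this negative result is weak.

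Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called genes, the real split with 160, and the highest of the others gave 0. For lists, 10 of the 10 splits gave as many, the real split 2 and the highest of the others 8. In both cases 10 splits are too few for a share under 0.05. Every other split called more lists than the real split, so a list call at the preset correlation alone is weak. Those splits mix arrays of both groups on each side, so genotype is in part within their contrasts. Correlated genes within a list, a structure of the samples or the touch genes of wild type replicate 3 may be behind these calls. Which of them is was not tested.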
